A study of Homo sapiens with 4 samples.

How the data were processed

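The series measured ribosome-associated mRNA in primary human umbilical vein endothelial cells treated with histamine or with buffered salt solution as vehicle. The labels give a dose of 100 mM and a time of 2 h, and the dose is printed as the labels state it. Per the labels' series design, elongation was stopped with cycloheximide, lysates were separated on sucrose gradients, and RNA of the monosome and polysome fractions was reverse transcribed from oligo-dT with a radioactive nucleotide. The cDNA was hybridised to 4 nylon cDNA filters of 1 design, which were read on phosphorimaging screens with the Pathways software, per the labels.

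The deposited values are linear spot intensities, normalised by the authors within each filter. Per the labels' series design each spot was divided by the average of its filter; the deposited columns instead have a median of 1 on every filter, with means of 2.83 (control monosome), 2.90 (control polysome), 3.37 (histamine monosome) and 3.14 (histamine polysome). The scale before this step is unknown. Because a column can be rescaled freely, each was divided by its own mean, as the design describes, and the median was used as an alternative. The labels name a screen for spots above 1.1 times the background. No background column was used here, so every element was kept in the main setting, and values near the floor include background, which pulls their ratios toward 1. Arrays give no count depth; that each group had 1 filter limits the precision, and no interval was computed for a ratio. The 1 control sample whose title says polysome is called a monosome sample in its free-text description. Its group was taken from the title, and an exchange of both control filters was run as an alternative.

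Groups were taken from sample titles. The translation state was polysome over monosome, and the translation index was the histamine translation state over the control one, both per the series design, which also gives the limits for high (2.5) and low (0.4) ratios. Histamine over control was also computed within each fraction. Ratios were computed on the log2 scale. Of the 4132 elements, 1582 had 1 gene name in the platform annotation used here, 52 had several and 2498 were unnamed here; no gene was named from an element with several. The 1582 elements covered 1532 genes, and the gene identifiers of 1580 of these elements were found in a current table of human genes (assembly GRCh38.p14, used for names alone); no symbol needed updating.

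Before the data were examined, the comparisons, 25 gene lists, the alternatives and the rule for named genes were fixed. The rule named elements with 1 gene. For the index it took up to 10 at each end past a threshold, of at least median mean intensity, that also passed under median and lowess scaling (4 high and 5 low met it). For each other ratio it took the 4 highest and 4 lowest of at least median intensity. From each list it took the 2 highest and 2 lowest by index, or all members where 4 or fewer were measured, with no limit on intensity. It also held 14 genes to be named wherever measured, of which only JUNB was named on the array. Genes named outside the rule are said to be chosen after their values were seen, which also holds for bright elements, for repeat elements and for members given only as a list's examples in ratios other than the index. A gene with several elements has the mean of their log2 values.

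For lists with 5 or more measured genes, the median was placed among 10000 random lists of the same size, drawn from 10 intensity classes to match; a percentile outside 2.5 to 97.5 is called outside the central 95%. This describes these filters and is not a test across replicates. Pairs of elements of the same gene were set against random pairs from the same intensity classes. The alternatives were median scaling, quantile normalization, lowess scaling of each ratio on intensity (span 0.3), elements of at least median intensity, elements above 1.1 times the filter's 5th percentile on all filters, an offset of 0.1 of the filter mean, 1 value per gene, and exchanged control filters. Division by the mean without the brightest 1% of elements, and the exchange of control filters for the index of the genes named by it, were added after seeing the data.

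The calculations were tested on simulated filters built from the real elements, with noise of SD 0.28 on the log2 scale per value, the spread of the interaction. For the translation index over 4132 elements, 26% of elements changed 2-fold, 80% of those changed 4-fold and 100% of those changed 8-fold were at or above 2.5, with 50 elements simulated at each fold. Among unchanged elements 0.483% were at or above 2.5 and 1.88% at or below 0.4. The changed elements entered the mean of the simulated histamine polysome filter, so these shares are not centred as the data are. Lists of 15 genes shifted by 0.5 on the log2 scale lay outside the central 95% in 73% of draws, and unshifted lists in 6%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.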

Results

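Primary human umbilical vein endothelial cells, the cells that line the vein of the umbilical cord, were treated for 2 h with histamine or with its buffer vehicle. Histamine is an inflammatory mediator that acts on endothelial cells through receptors coupled to calcium and protein kinase C signalling. Ribosome-bound mRNA was then separated on sucrose gradients into a monosome fraction, of mRNA with a single ribosome, and a polysome fraction, of mRNA with several. Labelled cDNA from each fraction was hybridised to 1 cDNA filter, so the 4 groups (control monosome, control polysome, histamine monosome and histamine polysome) held 1 filter each. There were no replicates. All ratios below therefore describe these 4 filters, carry no replicate error and were not tested for significance. Each filter gave a value for 4132 array elements, of which 1582 carried the name of exactly 1 gene. Between 76.9% and 82.6% of the elements of a filter lay under 2 times its median. On the deposited scale, with a median of 1, the 5th percentile of a filter was 0.506 to 0.603. The brightest 1% of elements (42 elements) held from 28.7% of the summed signal on the control polysome filter to 41.5% on the histamine monosome filter. Ratios at or above 2.5 or at or below 0.4, the limits given in the series design, are called past a threshold.

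The translation state, the polysome signal divided by the monosome signal, ranked mRNAs by how much of their ribosome-bound message sat on several ribosomes. The rankings here and for the other ratios cover elements with 1 gene name and at least median intensity, and unnamed elements can lie beyond them (23 of the 120 elements at or above 2.5 in control cells had 1 gene name). In control cells the translation state was highest for PTMA (5.47), which encodes the small acidic nuclear protein prothymosin alpha. SNRPD2 (3.99), a core protein of the spliceosomal particles, ARPC2 (3.78), a subunit of the actin-nucleating Arp2/3 complex, and DHPS (3.62), the enzyme that begins the hypusine modification of a translation factor, followed. The lowest control values belonged to SMARCD2 (0.180), a subunit of the SWI/SNF chromatin remodelling complex, to PRKCA (0.228), a protein kinase C, to SON (0.246), a nuclear speckle protein, and to the stress kinase gene MAPK8 (0.267). In histamine-treated cells PTMA again stood first at 5.71. It was followed by EFNB1 (4.85), an ephrin ligand, SRP9 (4.36), a component of the signal recognition particle, and the transcription factor gene MEF2D (4.17). ESR1 (0.221), an oestrogen receptor gene, PTPRN (0.254), SON (0.282) and SMARCD2 (0.291, not past the threshold after lowess scaling) were lowest there. In control cells 120 elements were at or above 2.5 and 51 at or below 0.4; in histamine-treated cells the numbers were 228 and 39. The high elements shared by both conditions numbered 83, against 6.62 for independent lists, and the shared low elements 15, against 0.481. These expectations are too small, because they ignore intensity. Of the high elements, 117 of 120 in control and 224 of 228 in histamine-treated cells had at least median intensity. Of the low ones, 35 of 51 and 36 of 39 had. Across the 4132 elements, which are not independent replicates, the log2 translation states of the 2 conditions, taken from different filters, correlated with Pearson's r = 0.618 and Spearman's rho = 0.524. Both splits depended on scaling. The histamine split was 185 high and 54 low elements when each filter was divided by its median and 87 and 89 after quantile normalization; the control split was 137 and 48, and 90 and 66. With the mean taken without the brightest 1% of elements, a scaling added after seeing the data, the splits were 85 and 89 in control and 151 and 75 in histamine-treated cells.

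**Figure D1:**
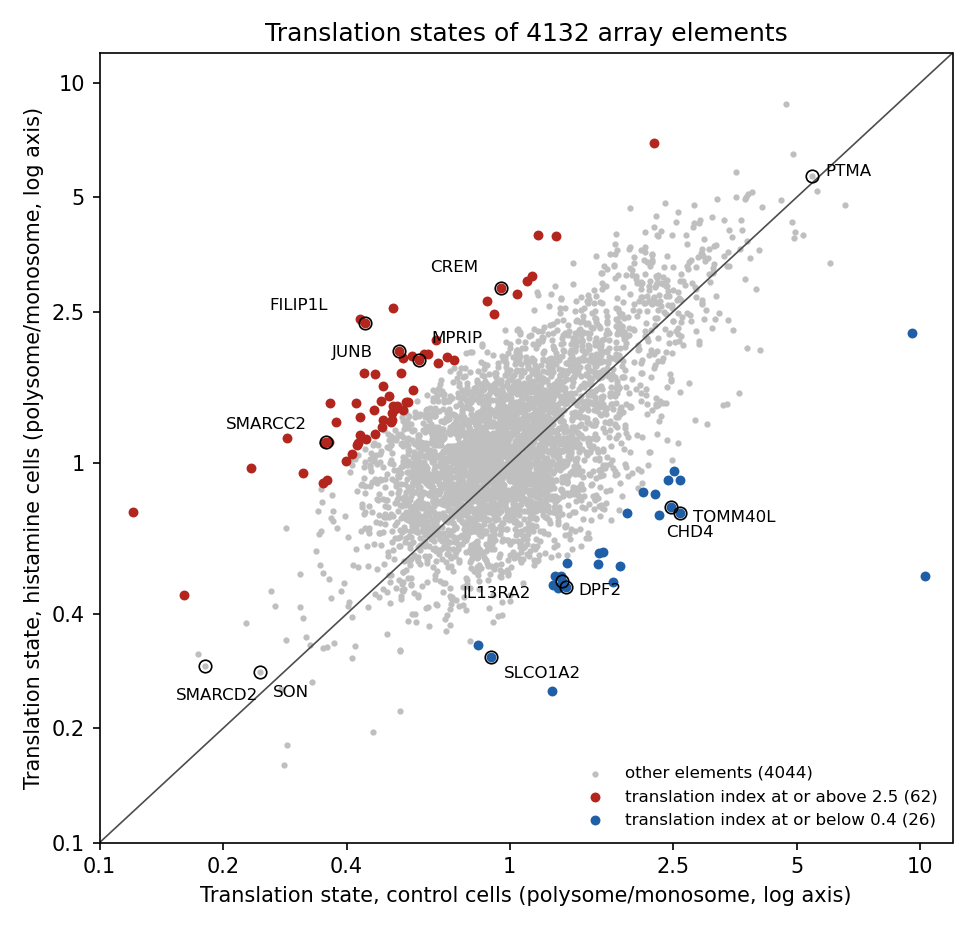
Translation state (polysome over monosome ratio of normalised intensity, log axes) of 4132 elements in control cells (horizontal) and histamine-treated cells (vertical); the line marks equal values, red points have a translation index at or above 2.5, blue points at or below 0.4, and open circles mark genes named in the text. PTMA lies near the line at the upper end, SON near it at the lower end, and FILIP1L and JUNB lie well above it.

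Of the fixed gene groups, 1 had a median control translation state outside the central 95% of random lists, the genes of the actin cytoskeleton and contraction. Of 19 measured members, 15 had a translation state above 1 (12 after quantile or lowess scaling), and 2 of them, ARPC2 and ACTB (2.85, the mean of 2 elements), were at or above 2.5. The list's median of 1.28 lay at the 98.5th percentile of 10000 random lists matched on intensity. In histamine-treated cells the median was 1.29, at percentile 90.3, with 3 members at or above 2.5: ACTB (3.41), ARPC2 (3.84) and CAPZB (2.66), the last chosen after its values were seen. ACTN1 (0.412), an actin crosslinker measured by a dim element (mean intensity 0.209 times the filter average), was the lowest member in control cells. Over the 80 list medians of all ratios, 2 lay outside the central 95%, where 4 would by chance. When only elements of at least median intensity were kept, the control median lay inside the central 95% of random lists, at percentile 96.3.

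The question the design put was which mRNAs changed their translation state with histamine. The translation index, the histamine translation state over the control one, was highest among brighter named elements for FILIP1L (5.27), a filamin-binding protein gene, whose translation state was 0.444 in control and 2.34 in histamine-treated cells. JUNB, an AP-1 transcription factor gene, followed at 3.68, from 0.537 to 1.97. SMARCC2, a core subunit of SWI/SNF, had an index of 3.18 and MPRIP, which targets myosin phosphatase to the actin cytoskeleton, 3.11. The lowest indices were those of TOMM40L (0.283), a homologue of a mitochondrial import channel, and CHD4 (0.309), the helicase of the NuRD chromatin complex. The transporter gene SLCO1A2 (0.342), DPF2 (0.344), a further SWI/SNF subunit, and IL13RA2 (0.364), a decoy receptor for interleukin 13, were also low. Passing under average, median and lowess scaling was part of the rule that chose these 9 genes, so it says nothing of their stability; with an offset, which was not part of it, DPF2 and IL13RA2 lost the threshold. The description of the control polysome sample conflicts with its title, and with the control filters exchanged SLCO1A2 (0.277) alone of the 9 stayed past its threshold: FILIP1L had 1.04, JUNB 1.06 and MPRIP 1.12, and SMARCC2 (0.405), TOMM40L (1.92) and CHD4 (1.88) turned direction. The titles, which were used, pair filters that correlated across elements at r = 0.944 (monosome) and 0.941 (polysome), against 0.840 to 0.892 for the other pairs. The 4 filters reached these values by different routes. For JUNB the polysome signal rose from 1.41 to 3.63 times the filter average, while for FILIP1L the monosome signal fell from 2.01 to 0.440 and the polysome signal went only from 0.892 to 1.03. For TOMM40L and CHD4 the polysome signal fell (ratios of 0.278 and 0.284), and for SLCO1A2 the monosome signal rose 4.27-fold.

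**Figure D2:**
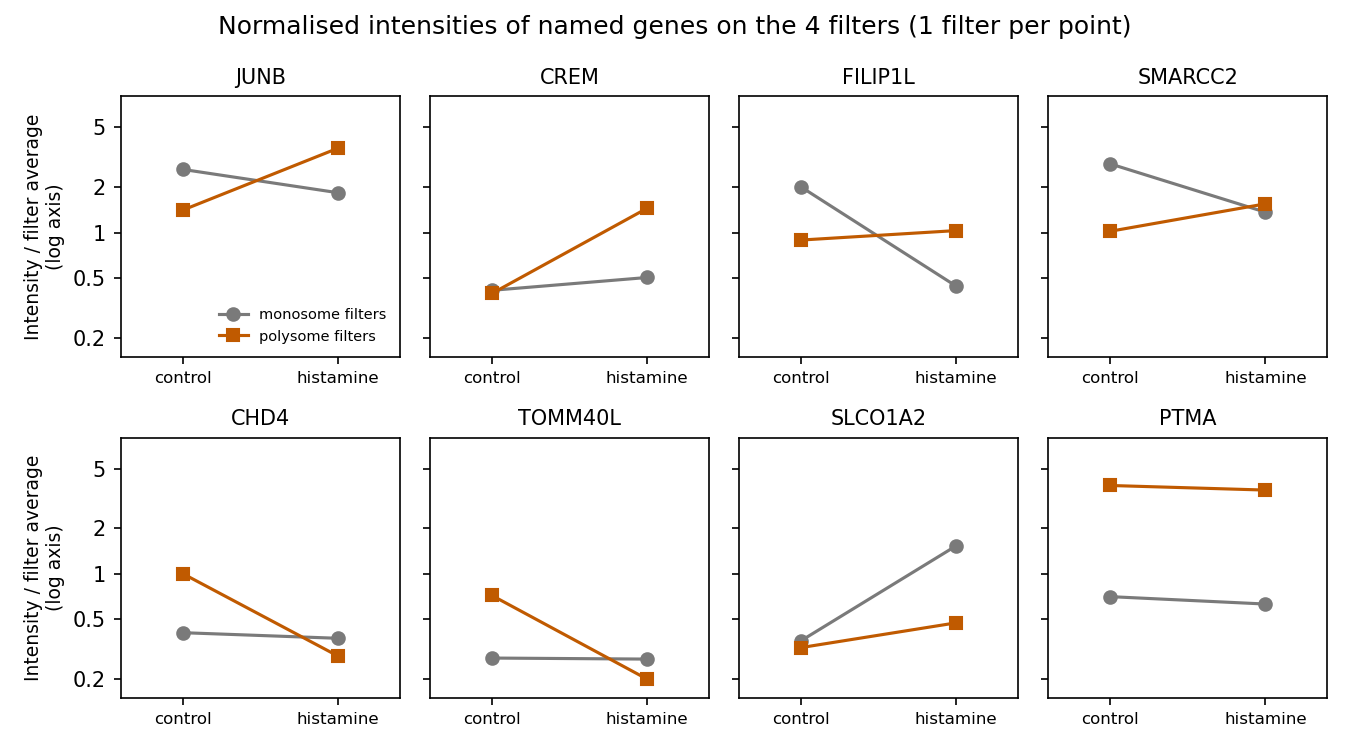
Normalised intensity (signal over filter average, log axis) of 8 named genes in control and histamine-treated cells, with grey circles for the monosome filters and orange squares for the polysome filters; each point is 1 filter, so no error bar is drawn. JUNB and CREM go up in polysomes, FILIP1L goes down in monosomes, CHD4 and TOMM40L go down in polysomes, SLCO1A2 goes up in monosomes, and PTMA stays high in polysomes in both conditions.

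Over all elements, 62 had a translation index at or above 2.5 and 26 at or below 0.4, of which 26 and 9 carried a single gene name. The elements without a name included the extreme values, 6.15 for element 447 and 0.0490 for element 3197. The split between high and low depended on the scaling of the filters: 70.5% of the elements past a threshold were high with division by the average, 40.2% (35 high, 52 low) with division by the median and 39.3% (35 high, 54 low) after quantile normalization. The median element itself had a log2 index of 0.17 with average scaling and 0.04 with median scaling, so an index a little above 1 was the usual value.

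None of the 16 fixed gene lists with at least 5 measured genes had a median translation index outside the central 95% of random lists. Immediate early genes, the first genes transcribed after a stimulus, had a median index of 1.25 over 16 genes (percentile 81.3). JUNB was the 1 member at or above 2.5; the kinase phosphatase gene DUSP6 was at 2.27, and IER2 (0.667) and EGR3 (0.605) were the lowest members. All 6 endothelial identity genes had an index above 1 with average scaling, and 5 with median, quantile or lowess scaling. Their median was 1.24 (percentile 76.5). Members ran from EPHB4 (1.09) and CDH5 (1.12), the gene of VE-cadherin, to PROCR (1.40) and KDR (2.11), a VEGF receptor gene. KDR was dim (mean intensity 0.239 times the filter average), and its histamine monosome signal lay under that filter's 5th percentile. With average scaling, cell cycle and DNA replication genes had the highest percentile, 92.2, with a median of 1.35 over 11 genes. With lowess scaling the actin list stood at percentile 92.4. Of the cell cycle genes, MKI67 (2.41), a proliferation marker, and the cell cycle inhibitor CDKN1B (2.32) were highest, MCM3 (0.635) and CDC6 (0.607) lowest. CDC6 was dim (mean intensity 0.152 times the filter average), with signals under the 5th percentile of their filters. The kinases and repressors that control translation had a median of 1.23 over 6 genes (percentile 63.7), with MAPKAPK2 at 2.46 and RPS6KA3 at 0.728.

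Among the remaining lists, medians were 1.23 for 7 apoptosis regulators (percentile 67.4; BAK1 1.48, FADD 0.555), 1.19 for 10 extracellular matrix and integrin genes (percentile 64.5; NID2 1.93, NID1 0.715), and 1.18 for 9 cell junction genes (percentile 61.1; OCLN 1.96, CTNNB1 0.834). The log2 index of NID1 went from -0.48 with average scaling to 0.0016 with lowess scaling. Proteasome genes had 1.16 over 6 genes (percentile 59.3; PSMB10 1.79, PSMA1 0.645), actin genes 1.14 over 19 (percentile 52.2; ACTN1 2.40, LIMK1 0.491), and vasoactive genes 1.13 over 6 (percentile 53.5; GCH1 1.45, ECE1 0.753). NID2, LIMK1 and ACTN1 were dim, with mean intensities of 0.180, 0.207 and 0.209 times the filter average. Each had a signal under a filter's 5th percentile. Translation factors had 1.13 over 5 genes (percentile 47.3; PABPC4 1.56, EIF1 0.868), and genes of the NF-kappaB pathway 1.01 over 5 (percentile 38.1; TRAF1 1.86, MYD88 0.857). Lower medians were those of fibroblast markers (0.959 over 7 genes, percentile 22.3; COL6A1 2.19, THY1 0.585), the Gq, calcium and protein kinase C list (0.940 over 10, percentile 13.4; RGS4 1.70, GRK2 0.475), heat shock proteins and chaperones (0.929 over 6, percentile 11.9; ST13 1.91, DNAJB1 0.590) and oxidative phosphorylation (0.904 over 5, percentile 13.4; COXFA4 1.13, NDUFA5 0.609). No member of the lists in these sentences passed a threshold with average scaling. GRK2 passed the lower threshold after quantile normalization (-1.37 on the log2 scale) and lowess scaling (-1.38).

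The other 9 lists had fewer than 5 measured genes and are given by value. Of 4 inflammatory genes, IL15 had an index of 2.68, CXCL10 2.28, TNFSF10 1.50 and CX3CL1 0.897; IL15 lay under the threshold with median, quantile and lowess scaling and with the offset. Secretory pathway genes were KDELR1 (1.41), SRP9 (1.31), SRPRA (0.923) and SSR1 (0.804). Single members were RPL31 (1.16) for ribosomal proteins and PROCR for coagulation. For glycolysis PFKL had 1.17 and LDHA 1.15, the mean of 3 elements that disagreed (0.725, 1.40 and 1.50). With lowess scaling the lowest of these LDHA elements had a log2 index of 0.03. Markers of other cell types included CSPG4 (1.20) and CNN1 (0.812) for mural cells, CSF1R (1.09) and CD79B (0.786) for leukocytes and platelets, and CLDN4 (0.844) for epithelium; no red blood cell marker was named on the array as analysed here. Most were dim, but LUM and CSF1R reached mean intensities of 1.04 and 1.21 times the filter average.

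Within the polysome fraction, histamine over control was highest among brighter named elements for CREM (3.68), a cAMP-responsive transcription factor gene, and JUNB (2.57). RGN (2.20) and GTF3C1 (2.19), a subunit of transcription factor IIIC, came next among these, without passing the threshold. TOMM40L (0.278), CHD4 (0.284), ZMYND8 (0.376), a chromatin reader, and ALDH9A1 (0.392), an aldehyde dehydrogenase, were lowest; ALDH9A1 and ZMYND8 no longer passed with median scaling, nor JUNB with the offset. Immediate early genes as a list had a median ratio of 1.18, at the 98.6th percentile of random lists (2 of 80 list medians lay outside the central 95%, where 4 would by chance), and 11 of the 16 were above 1 (12 with median, quantile or lowess scaling). Beside JUNB, and chosen after their values were seen, RCAN1 (2.10), JUN (1.85) and NR4A3 (1.79) were high, as was DUSP6 (1.97), while IER2 (0.430) and EGR3 (0.516) were low. JUNB was the only member past a threshold. Fibroblast markers had a median of 1.02 in this fraction, at percentile 70.6. In all, 11 elements were at or above 2.5 and 23 at or below 0.4; with median scaling these were 18 and 10, with quantile normalization 11 and 8.

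**Figure D3:**
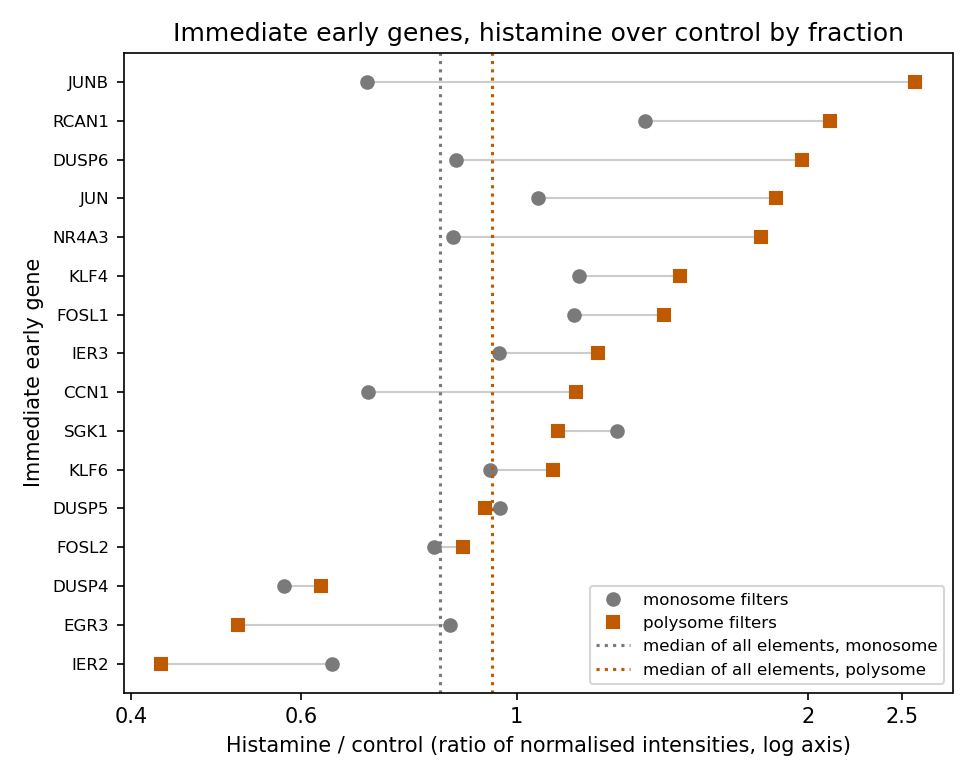
Histamine over control ratio of normalised intensity (log axis) for the 16 immediate early genes measured, with grey circles for the monosome filters and orange squares for the polysome filters; dotted lines mark the median of all elements in each fraction. Polysome ratios run from 0.430 for IER2 to 2.57 for JUNB, and 11 of the 16 lie above 1.

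Within the monosome fraction, SLCO1A2 (4.27) and ESR1 (3.25) had, among brighter named elements, the highest histamine over control ratios, ahead of IGHV5-78 (2.14), an immunoglobulin heavy chain segment, and PRDX3 (2.04), a mitochondrial peroxiredoxin. The lowest were FILIP1L (0.219), MPRIP (0.346), ELN (0.385), the elastin gene, and SSX3 (0.385). The last 3 did not pass the threshold with median scaling. At the high end, IGHV5-78 passed the upper threshold with median scaling (1.35 on the log2 scale). PRDX3 passed it after quantile normalization (1.50) and lowess scaling (1.35). Extracellular matrix genes had a median of 0.729 with 9 of 10 members below 1 (8 with median scaling, 7 with quantile or lowess scaling), at percentile 5.11; fibroblast markers had 1.06 at percentile 96.9. In total 9 elements were at or above 2.5 and 18 at or below 0.4, against 14 and 5 with median scaling and 22 and 10 after quantile normalization. The median element had a log2 ratio of -0.26 with average scaling and -0.01 with median scaling in this fraction. No element passed the same threshold in both fractions. Independent lists of these sizes would share 0.0240 high and 0.1002 low elements, values that ignore intensity. The lack of shared elements therefore does not show that the fractions differed.

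Without replicates, the spread of the filters' contrasts and of elements of the same gene describe the variation. The difference between fractions had an SD over elements of 0.58 on the log2 scale, that between treatments 0.33, and their interaction, which is the log2 index divided by 2, 0.28. For 36 genes with 2 or more elements (65 pairs), the log2 index of elements of the same gene had an SD of 0.46, against 0.56 for random pairs, which placed it at percentile 3.25, inside the central 95% of random pairs; for the 19 brighter pairs the values were 0.54 and 0.53. The index had the same sign in 50.8% of the 65 pairs. For the control translation state the SD was 0.39 against 0.58 (percentile 0.0400), and for the histamine one 0.51 against 0.59 (percentile 9.40, inside the central 95% too). The 65 pairs came from 86 elements, and genes with more than 2 elements gave pairs that share an element. Random pairs were drawn separately, so these percentiles may be too extreme. DHPS, whose 2 elements had indices of 0.423 and 0.424, and EIF2B5, with 0.648 and 1.62, are examples of close and of poor agreement. The SD of the log2 index was 0.58 in the dimmest 1 of 5 intensity classes and 0.56 in the brightest.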

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

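Of 112 elements of named genes looked at, 12 moved in opposite directions with histamine in the 2 fractions, under average and median scaling, by more than the SD between elements of the same gene in each fraction under average scaling. Over all 4132 elements, 255 (6.17%) did so, against 10.7% of the 112. Many of the 112 had been chosen for a high or low index, the ratio of these same movements. All of the 12 except IL15 were named for a high or low index, either by the index rule or within their list. Opposite movement is thus largely built into the selection, and these shares cannot be compared. With 1 filter per group the difference was not tested, and this comparison of fractions was chosen after the data were seen. With average scaling the median of all elements was a monosome ratio of 0.834 and a polysome ratio of 0.943. A monosome ratio somewhat below 1 was therefore the usual value. JUNB had a translation index of 3.68, with a polysome ratio of 2.57 and a monosome ratio of 0.700. SMARCC2, a SWI/SNF subunit, had an index of 3.18 from ratios of 1.52 and 0.478. The cytokine gene IL15 (2.68), the stress kinase substrate MAPKAPK2 (2.46), the proliferation marker MKI67 (2.41) and the actin crosslinker ACTN1 (2.40) also had higher polysome and lower monosome signals after histamine. So did CDKN1B (2.32), the tight junction gene OCLN (1.96) and the immunoproteasome gene PSMB10 (1.79). With median scaling the monosome decreases of JUNB, MAPKAPK2, CDKN1B, OCLN and PSMB10 were smaller than the SD between elements of the same gene. ACTN1 and MKI67 were dim, with mean intensities of 0.209 and 0.275 times the filter average. Their control polysome signals lay under 1.1 times that filter's 5th percentile. In the opposite direction, with less signal in polysomes and more in monosomes, were the receptor kinase gene GRK2 (0.475), IL13RA2 (0.364) and DPF2 (0.344), a SWI/SNF subunit.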

How the results depend on the processing

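Counts of elements past a threshold moved most; they are given as high and low, against 62 and 26 for the index, 120 and 51 for the control and 228 and 39 for the histamine translation state, 11 and 23 for the polysome and 9 and 18 for the monosome ratio. A count is called moved beyond 1.5 times, and the cause was not tested except where fewer elements entered. Median scaling gave 35 and 52 for the index (35 and 26 of them shared with average scaling), 18 and 10 for the polysome and 14 and 5 for the monosome ratio. Quantile normalization gave 35 and 54 for the index, 87 and 89 for the histamine translation state, 8 low polysome ratios, and 22 and 10 monosome ratios. Lowess scaling gave 32 and 50, 103 and 77 for the histamine translation state, 17 and 13 for the polysome ratio and 7 low monosome ratios; it moved the actin list's index, relative to all elements, from 0.02 to 0.23 (log2). With 2066 elements of at least median intensity the index gave 30 and 16 and the polysome ratio 7 and 14, the actin list's control translation state was 0.44 (percentile 96.3, against 0.40), and the matrix list's index went from 0.08 to -0.12. With 3104 elements above the stand-in background the index gave 30 and 14. The control translation state gave 32 low elements there and the polysome ratio 5 and 14. The immediate early polysome ratio went from 0.33 to 0.47 because EGR3 (0.516) and DUSP4 (0.629) left. Their histamine polysome signals lay under that filter's limit, so the limit follows the change in part. The offset gave 19 and 9 for the index, 26 low control translation states, 5 and 6 polysome ratios and 8 low monosome ratios. With 1 value for each of 1532 genes the index gave 26 and 9, the control translation state 22 and 24, the histamine one 55 and 12, the polysome ratio 4 and 9 and the monosome ratio 2 and 5.

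Exchanging the control filters gave 582 and 253 for the index, 51 and 120 for the control translation state, 95 and 42 for the polysome and 72 and 307 for the monosome ratio; 7 of the 62 high and 3 of the 26 low index elements were shared. Filters of the same fraction by title correlated across elements at r = 0.944 (monosome) and 0.941 (polysome), against 0.840 to 0.892 for the other pairs, and the translation states of both conditions at r = 0.618, whose sign the exchange turns; these values favour the titles. For the 9 genes named by the index, an exchange added after seeing the data left SLCO1A2 past its threshold (-1.85 on the log2 scale) and turned SMARCC2 (-1.30), TOMM40L (0.94) and CHD4 (0.91); the other 5 lost the threshold. The added scaling without the brightest elements, chosen after seeing the data, gave 85 and 89 for the control translation state, 151 and 75 histamine ones, 17 and 13 polysome ratios and 10 low monosome ratios, and kept the index within 1.5 times (51 and 32). The spreads of the contrasts, of repeat elements and of intensity classes stayed within 1.5 times under the 5 alternatives run on them. Of 215 alternative values of counts, spreads and lists, 152 stayed and 63 moved. Part of this was fixed in advance: median scaling cannot move spreads or list values relative to all elements, nor the exchange the histamine translation state. A further 13 list values were not computed because fewer than 5 genes were left. Among 714 alternative values of named genes, the 3 just given, all under the exchange, changed direction from a value past a threshold. Only the 38 main values past a threshold could be counted so. The limits on intensity and background leave the value of a kept element as it was. The 9 genes named by the index were chosen for passing under median and lowess scaling; all 9 also passed under quantile normalization, and DPF2 and IL13RA2 alone lost the threshold with the offset (-1.32 and -1.18 on the log2 scale). How far background limits the dim elements was not measured, because no background value was used. At least 76.9% of each filter lay under 2 times its median, which describes the spread of signals and not the background.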

Other observations

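The tests of explanations in this part, and the remarks on DHPS and on bright elements, were chosen after the results were seen; the index counts, the immediate early gene list and median scaling were fixed before. DHPS, the enzyme of hypusine synthesis, was measured by 2 elements that agreed. Their control translation states were 3.62 and 3.38, their histamine ones 1.53 and 1.43, and their indices 0.423 and 0.424, just short of the lower threshold with average scaling.

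More elements lay above the upper limit of the index than below the lower one with division by the average, 62 against 26 (70.5% high), but not with median scaling (40.2% high), quantile normalization (39.3%; 35 high, 54 low) or lowess scaling (39.0%; 32 high, 50 low). A spread of unchanged elements cannot be told apart from real changes, because what it gives depends on its SD and centre: a normal curve about the observed median gives 64.7 above and 11.1 below with a robust SD and 83.6 and 16.6 with the ordinary SD, and simulated unchanged elements, centred at 0.910, had 0.483% above and 1.88% below. A filter average set by a few bright elements cannot be told apart from other causes of the shift: with the brightest 1% left out of the mean 61.4% were high (51 and 32), but this moves every index by the same amount, as median scaling does, and so decides nothing. The proper scaling and a heavier-tailed error stay open, and no biological explanation was tested, because each condition had filters of its own.

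Immediate early genes had a median polysome ratio of 1.18 (percentile 98.6), with 11 of 16 above 1 and JUNB alone past a threshold. Chance among the 80 list medians looked at (16 lists and 5 ratios) may account for it: 2 medians lay outside the central 95% where 4 would by chance, and in 89.3% of 10000 shuffles of gene names within intensity classes some median lay as far out (54.9% to 97.7% over the scalings, the offset and the median intensity filter). The limit above the stand-in background, a setting fixed before the data were examined, gave 1.26%, which speaks against chance under that setting. It dropped EGR3 and DUSP4 for their low histamine polysome signals, so it selects in part on the change. The shuffles under it drew from the genes it kept, and how far this selection matters was not tested. The settings therefore disagree on chance. More mRNA in both fractions, rather than a shift between them, cannot be told apart from a shift: the list's index lay at percentile 81.3 and its monosome ratio at 82.5. A response of these genes to histamine stays open and was not tested beyond these filters.

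With average scaling, the only scaling used for this count, the brightest elements shared a profile over the filters. The brightest 1% held 28.7% to 41.5% of a filter's summed signal and so weigh on its average. Under this scaling the median monosome ratio outside the brightest of 5 intensity classes was 0.833, so ratios above 1 were uncommon there. With median scaling the median element had a log2 monosome ratio of -0.01, so the contrast given next may depend on scaling. Of the brightest 1%, 22 of 42 had translation states below 1 in both conditions and histamine over control ratios above 1 in both fractions (52.4%, exact 95% binomial interval 36.4% to 68.0%, which treats elements as independent), against 12.9% (101 of 784) in the rest of the brightest of 5 intensity classes and 3.81% of the other elements; they included INPP5J, CALD1, MALL, CUX1 and SPIB, a lymphoid transcription factor gene. A detector whose values pile up at a fixed maximum is argued against by only 5 elements, over the 4 filters, within 10% of a filter's maximum (each maximum included). Compression of bright signals below such a maximum would not show in this count and stays open. An intensity-dependent response of the filters could give a profile that grows more frequent with intensity, and cannot be told apart from real differences: 3 of the 42, among them an ACTB element with 3.38 and 3.30, had translation states at or above 2.5 in both conditions, which is too few to exclude it. A target shared by unrelated clones stays open too. Only 2 genes had both another element and an element with the profile in the brightest of 5 intensity classes, and both disagreed. In LDHA the bright element, 55th in intensity and so outside the 42, had a control translation state of 0.817 where the others had 2.03 and 1.89. The NGB elements were both below 1 in translation state but differed in the rest of the profile. No biological explanation was tested.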
